A study of Rattus norvegicus with 8 samples.

How the data were processed

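Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on kidneys of Sprague Dawley rats with an antibody to Hnf4a at 3 ages, namely embryonic day 20 (E20), postnatal day 13 (P13) and adult (8 weeks), and with an antibody to p300 in the cortex of adult kidneys. Each of the 4 ChIP libraries had 1 matched input DNA library of the same tissue and age, so the series comprised 8 samples with 1 library per group. Per the labels' protocols, frozen kidneys, or cortex shaved from the outer 1 mm of a frozen kidney, were fixed in 1% formaldehyde for 15 min, sonicated and immunoprecipitated, and fragments of 200 to 400 bp were sequenced. The adult kidneys were male and the younger kidneys were unsexed, per the labels.

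The files analysed were 4 peak lists, 1 per ChIP library. Per the file headers, the authors called peaks with HOMER findPeaks in its transcription factor mode, separately for each library and against its own input, without pooling. Peaks had to pass a false discovery rate of 0.001, to hold at least 4-fold more tags than the scaled input and at least 4-fold more than the surrounding 10 kb, and to have a Poisson p-value of at most 0.0001 in both comparisons. At most 1 tag was counted per position, per the file headers. The genome build was rn4, per the submitters' processing notes. The aligner and the HOMER version are not given in the sources used here.

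Each peak carried several values in the deposited lists. The normalized tag count is a signal, tags in the peak per 10 M total tags, as the authors' run gave it. The findPeaks score in the deposited lists was a whole number that equalled the normalized tag count multiplied back to the library's total tags. Because of the limit of 1 tag per position, this score has a ceiling near 2 tags per bp of the peak, which strong peaks reached. The fold over input in the deposited lists is the ratio of ChIP tags to scaled input tags. The p-value columns and the focus ratio, a fraction describing how tags are placed around the peak centre, were deposited by the authors and were not used beyond the thresholds the authors had set. These per-peak values belong to the authors' calls and were used to rank, filter or describe peaks within their own list, and a floor on the normalized tag count was tried as an alternative. Where values from several lists are given for a region or as medians, each describes its own library, and no change between ages is read from them. The highest normalized tag count was 97.8 at E20, 119.9 at P13 and 119.7 in adult, so the ceiling also differs between libraries. The 4 input libraries entered through the authors' calls alone and were not analysed here separately.

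Peak coordinates are given as in the files, on rn4. Peaks of different lists were called shared when they overlapped by at least 1 bp. The share expected by chance was taken from 100 circular shifts of one list along each chromosome, or from 20 for the p300 share of region classes. Distances between centres after a shift, and the shares within a distance, came from a single shift and carry no spread. The Hnf4a lists were merged into regions wherever peaks of different lists overlapped, and each region was classed by the ages at which it held a peak. Peaks were ranked by score, with ties broken by fold over input and then by position. They were split into 10 deciles of equal size within each list, from 1 (weakest) to 10 (strongest). Peaks per Mb were counted over the span between the first and last peak of any list on a chromosome. The share of tags in peaks is the value given per the file headers. In each list it exceeds what the normalized tag counts of the listed peaks add up to. It may therefore also cover tags outside the listed peaks. Shares carry exact Clopper-Pearson 95% intervals, and numbers of peaks carry exact Poisson 95% intervals. These intervals cover counting error only. With 1 library per group no test between ages or antibodies could be made, and no p-value is given. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The code for region classes was run on 20000 simulated regions of known class, and the class totals found differed from those made by 0. The simulated regions lay far apart and their peaks were nearly aligned. This result therefore checks the code only and does not cover displaced or crowded peaks. The shifts gave a chance share of E20 peaks in the adult list of 0.641%, against 0.617% for uniform placement.

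The main comparisons, the rule for named regions and most alternatives were fixed before the data were examined. The split into score deciles, the distances between peak centres, the summary by chromosome and the counts in genomic bins were added after the peak lists were seen. The named regions are the 2 with the highest authors' score in each of 5 kinds, namely regions called at all 3 ages, regions called in adult and not at E20, regions called at E20 and not in adult, p300 peaks with an adult Hnf4a peak and p300 peaks without one. The tie-break by fold over input was added after the ceiling of the score was seen. Planned summaries by distance to transcription start sites, by gene lists and by the Hnf4 motif were not run, because no rn4 gene annotation or sequence was used here and coordinates were not converted between builds. Regions are therefore given by position without a gene name. Alternatives covered the overlap rule, a stricter score, lists of equal length, a stricter fold over input and a common floor on the normalized tag count. The common floor, a 500 bp distance between centres and, for the overlap between pairs of ages, the limiting of all 3 Hnf4a lists to 1 length were chosen after seeing the data. Equal length for the region classes was planned.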

Results

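Binding of Hnf4a, a nuclear receptor that drives the expression of metabolic and transport genes in liver and kidney epithelium, was mapped in whole rat kidney at E20, P13 and adulthood. Binding of p300, a histone acetyltransferase recruited to active enhancers and promoters, was mapped in adult kidney cortex. The series asks how Hnf4a binding relates to the maturation of genes for drug metabolism and drug transport in the developing kidney. The ChIP libraries held 23.1 M tags at E20, 18.3 M at P13, 16.4 M in adult and 11.7 M for p300, per the file headers. The headers gave the share of tags lying in peaks as 14.3%, 22.3%, 33.4% and 18.0%, which is more than the listed peaks' normalized tag counts add up to. Each group was represented by 1 library, so differences between ages have no replicate check. The adult kidneys were labelled male and the younger ones unsexed.

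The number of Hnf4a peaks was higher at each later age. The E20 list held 38145 peaks (exact Poisson 95% interval 37763 to 38530), the P13 list 52541 (52093 to 52992) and the adult list 79871 (79318 to 80427). The P13 list was 1.38 times as long as the E20 list, and the adult list was 2.09 times as long. This order was opposite to that of sequencing depth, as the adult library held 0.708 times the tags of the E20 library. It followed the share of tags in peaks given in the headers, which in adult was 2.33 times that at E20. Before the authors' filters against input and local signal, putative peaks numbered 128649 at E20, 124949 at P13 and 149092 in adult. At that step E20 exceeded P13. Of the putative E20 peaks, 69.7% were removed by the authors' comparison with input, against 55.1% at P13 and 40.8% in adult. The median fold over input of the retained peaks was 11.8 at E20, 13.6 at P13 and 15.6 in adult. Among peaks at or above the E20 median of 17.3 tags per 10 M, the adult list was 2.60 times as long as the E20 list. This floor is per total tags and does not correct for the differing share of tags in peaks.

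Most sites bound at E20 were also called later. Of the E20 peaks, 79.3% (95% interval 78.9 to 79.7) overlapped an adult peak and 76.2% (75.8 to 76.6) a P13 peak, where shifted lists gave 0.652% and 0.449%. Of the P13 peaks, 85.6% (85.3 to 85.9) overlapped an adult peak. In the other direction, 37.9% (37.5 to 38.2) of the adult peaks overlapped an E20 peak and 56.3% (56.0 to 56.7) a P13 peak. With all 3 Hnf4a lists limited to their 38145 highest-scoring peaks, P13 and adult shared 74.6% (74.1 to 75.0), E20 and P13 shared 67.7% (67.2 to 68.2), and E20 and adult shared 60.2% (59.7 to 60.7). At this length the P13 list overlapped each of the other lists more than these overlapped each other, by more than the counting intervals.

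Merging the 3 Hnf4a lists gave 92922 regions. Regions called at all 3 ages numbered 26965 (29.0%), regions called at P13 and in adult but not at E20 numbered 18139 (19.5%), and regions called in adult only numbered 31347 (33.7%). Fewer regions were called at E20 only (5614), at P13 only (5291), at E20 and P13 only (2146) or at E20 and in adult but not at P13 (3420). Of the regions called at both E20 and adulthood, 88.7% were also called at P13 (95% interval 88.4 to 89.1). Of the 49486 adult regions that lacked an E20 peak, 36.7% (36.2 to 37.1) already held a P13 peak. Of the P13 regions that lacked an E20 peak, 77.4% (76.9 to 78.0) were called again in adult, whereas 37.9% (36.9 to 38.9) of the E20 regions that lacked a P13 peak were. Regions called at E20 and not in adult numbered 7760. These numbers change with list length: with lists of equal length, 21146 regions were called at all 3 ages and 7717 in adult only, so adult-only regions were then the smaller class. At this length 15075 regions were called in adult and not at E20, and by construction the same number was called at E20 and not in adult.

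**Figure D1:**
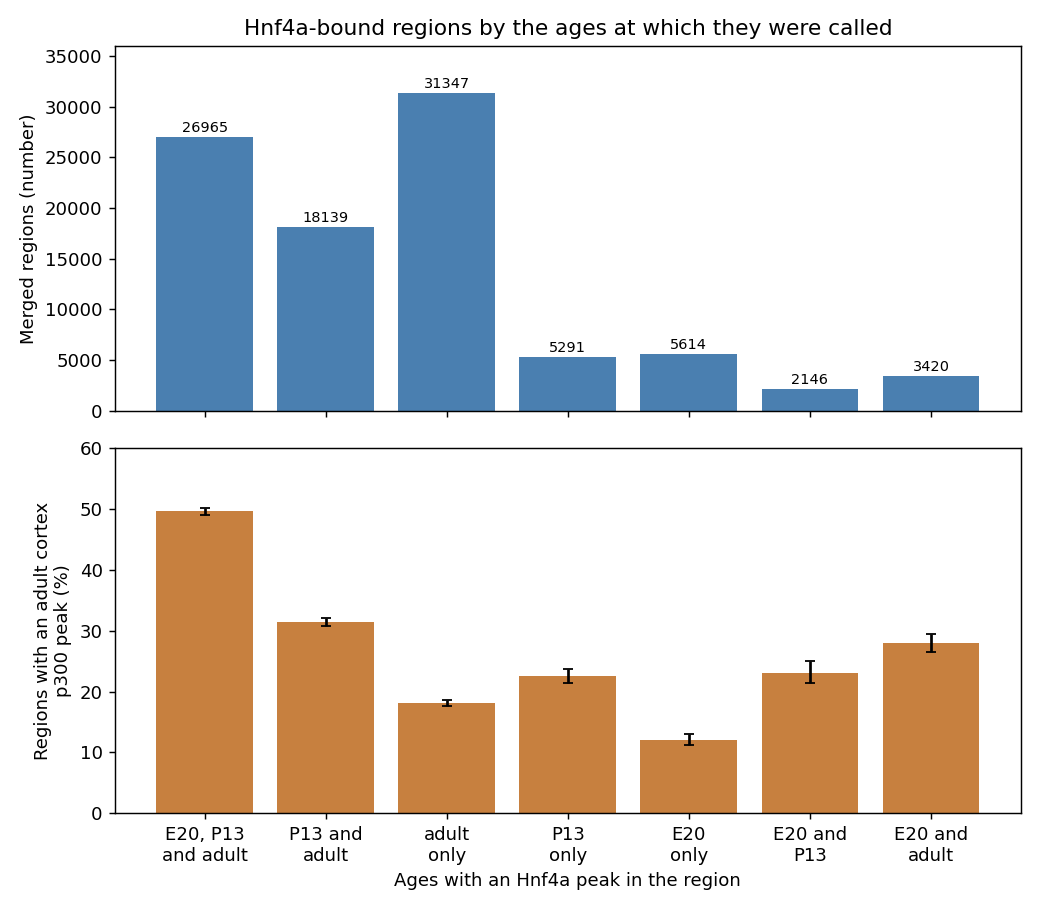
The upper bars give the number of merged Hnf4a regions for each combination of ages, and the lower bars give the percentage of those regions that overlap an adult cortex p300 peak, with exact 95% binomial intervals. With the full lists, regions called in adult only are the most numerous (31347), and regions called at all 3 ages have the highest p300 share (49.7%).

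Sites shared between ages were the stronger ones in their list. In the adult list, peaks with an E20 peak had a median of 46.4 tags per 10 M and peaks without one had 17.1, at median score percentiles of 75.3 and 35.7. In the E20 list, peaks with an adult peak had a median of 19.5 and peaks without one had 13.0. The share of adult peaks with an E20 peak was 9.08% in the weakest decile and 89.4% in the strongest, and the share with a P13 peak was 13.9% and 97.7%. The share of E20 peaks with an adult peak was 57.6% in the weakest decile and 98.1% in the strongest.

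**Figure D2:**
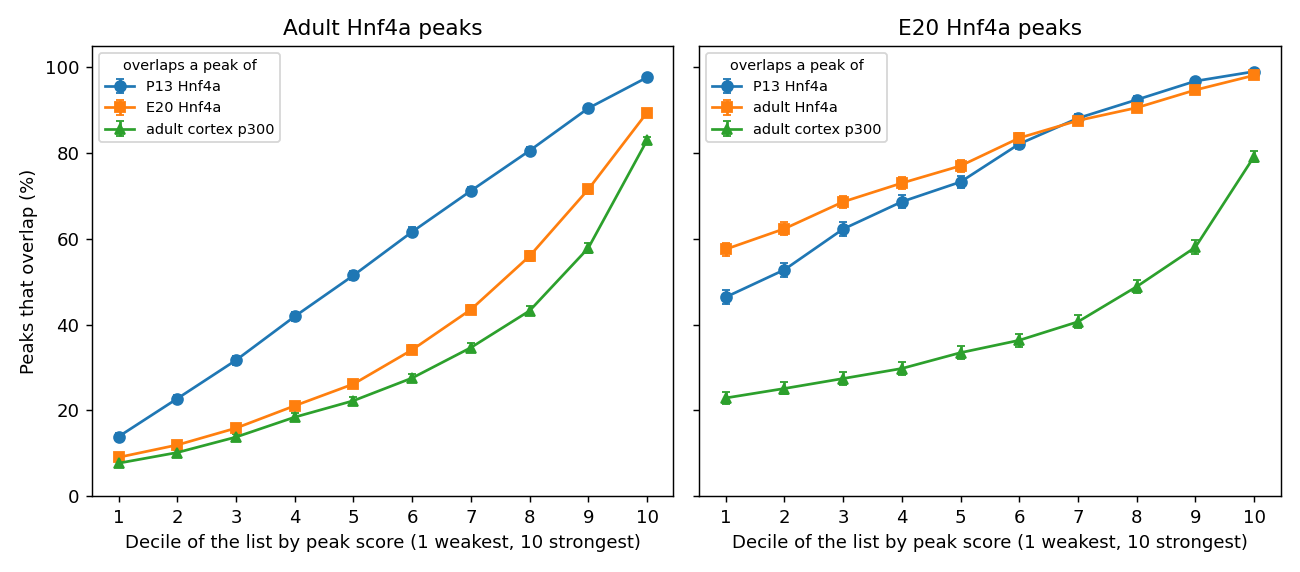
Percentage of adult (left) and E20 (right) Hnf4a peaks that overlap a peak of another list, by decile of the list from the weakest (1) to the strongest (10) score, with exact 95% binomial intervals. Overlap is higher in stronger deciles for every list, from 9.08% to 89.4% for adult peaks with an E20 peak.

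The strongest regions called at all 3 ages lay on chromosome 1 (coordinates on rn4). The adult peak at 99323958 to 99324054 had 119.7 tags per 10 M and 123-fold enrichment over input, with 118.3 at P13, 89.5 at E20 and a p300 peak of 62.3. The adult peak at 155690498 to 155690594 also had 119.7, with 107.9 at P13, 73.5 at E20 and a p300 peak of 63.1. These values are each library's own and have different upper limits, the highest in a list being 97.8 at E20, 119.9 at P13 and 119.7 in adult. Both peaks were at the ceiling of the adult score, which 103 adult peaks reached, and all 103 of them lay in regions called at all 3 ages. Their fold over input was also equal, at 123-fold, so their order followed position and is not a ranking by strength.

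The strongest adult peak without an overlapping E20 peak lay on chromosome 10 at 87732143 to 87732239, with 119.1 tags per 10 M in adult, 101.9 at P13 and a p300 peak of 105.7. An E20 peak centre lay 288 bp away without overlapping it. The next lay on chromosome 19 at 54452397 to 54452493, with 118.5 tags per 10 M, 122-fold enrichment over input and a p300 peak of 64.8. Its nearest E20 peak centre was 5367 bp away, and a P13 centre lay 128 bp away. The strongest E20 peak without an adult peak lay on chromosome 7 at 137629966 to 137630078, with 83.9 tags per 10 M at E20 and 42.0 at P13. Its nearest adult Hnf4a centre was 8748 bp away and its nearest p300 centre 10591 bp away. The next, on chromosome 3 at 6144494 to 6144606, had 82.2 at E20 and 113.9 at P13, and an adult centre lay 150 bp away. Over all E20 peaks without an overlapping adult peak, 20.0% had an adult centre within 500 bp.

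Adult Hnf4a and p300 peaks coincided at many sites, although tissue and antibody differed together in this comparison. Of the 42537 p300 peaks in cortex, 59.8% (95% interval 59.4 to 60.3) overlapped an adult Hnf4a peak from whole kidney, where shifted lists gave 0.693%. Of the adult Hnf4a peaks, 31.9% (31.6 to 32.2) overlapped a p300 peak, against 0.370% by chance. The centres of overlapping p300 and Hnf4a peaks lay a median of 18 bp apart. A further 5.74% of p300 peaks overlapped an Hnf4a peak from E20 or P13 alone, and 34.4% (34.0 to 34.9), or 14641 peaks, overlapped none at any age. The p300 peaks without an adult Hnf4a peak had a median of 16.2 tags per 10 M, against 23.0 for those with one. The share with an adult Hnf4a peak was 35.3% in the weakest decile of p300 peaks and 72.6% in decile 7, but did not increase further, with 72.1% in decile 9 and 69.7% (68.3 to 71.1) in the strongest. The median distance of p300 peaks without an adult Hnf4a peak to an adult Hnf4a centre was 3315 bp, against 30797 bp for all p300 peaks after a shift.

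**Figure D3:**
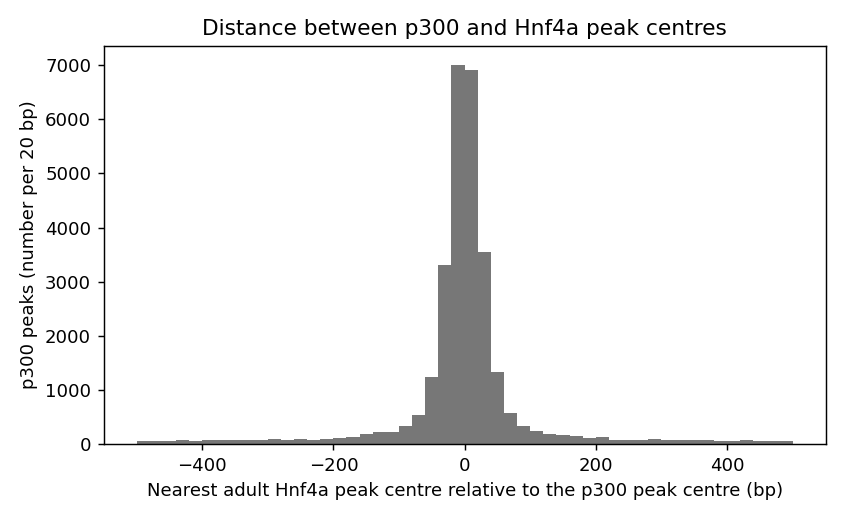
Number of p300 peaks by the position of the nearest adult Hnf4a peak centre relative to the p300 peak centre, in bins of 20 bp. The distances gather around 0, with 7005 and 6919 p300 peaks in the bins on either side of it.

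The strongest p300 peak that overlapped an adult Hnf4a peak lay on chromosome 17 at 48776057 to 48776183. It had 196.1 p300 tags per 10 M, and its Hnf4a peaks had 47.6 in adult, 23.4 at P13 and 17.7 at E20. The next lay on chromosome 3 at 128353727 to 128353853, with 195.3 p300 tags per 10 M and Hnf4a peaks of 96.5, 48.0 and 22.1 at the same ages. The strongest p300 peak without an adult Hnf4a peak, on chromosome 4 at 75901092 to 75901218, had 201.3 tags per 10 M but 4.48-fold enrichment over input, close to the authors' limit of 4. The next, on chromosome 6 at 138007659 to 138007785, had 173.1 with 11.2-fold enrichment, and its nearest adult Hnf4a centre was 537 bp away.

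The p300 share differed between the Hnf4a region classes. Because p300 was mapped in adult cortex alone, these shares do not describe p300 at E20 or P13. A p300 peak was present at 49.7% (95% interval 49.1 to 50.3) of regions called at all 3 ages, 31.4% (30.8 to 32.1) of regions called at P13 and in adult, and 18.1% (17.7 to 18.5) of regions called in adult only. Regions called at E20 only had the lowest share, 12.1% (11.3 to 13.0), and regions called at E20 and not in adult had 15.1% (14.4 to 16.0), against 23.0% (22.6 to 23.4) for regions called in adult and not at E20. The share was 22.6% (21.5 to 23.7) for regions called at P13 only and 23.1% (21.3 to 25.0) for regions called at E20 and P13. Shifted p300 peaks gave 0.419% of regions called at all 3 ages and 0.379% of regions called at E20 only. With lists of equal length, 34.6% of adult-only regions, 39.0% of the regions called in adult and not at E20 and 13.5% of those called at E20 and not in adult held a p300 peak. In the 50% of each list with the higher scores, the share of regions called at E20 and not in adult was 7.92%. With all 4 lists limited to 38145 peaks, p300 overlapped 48.3% (47.8 to 48.8) of adult, 44.5% (44.0 to 45.0) of P13 and 38.3% (37.8 to 38.8) of E20 Hnf4a peaks. In the full lists the order was the reverse, with 31.9% of adult, 39.1% of P13 and 40.2% of E20 peaks, so it depends on list length.

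The place of regions called at all 3 ages in this order changed with peak strength. In all 10 adult deciles, peaks of regions called at P13 and in adult had a higher p300 share than adult-only peaks, from 9.02% against 7.74% in the weakest decile to 74.0% against 60.2% in the strongest. The gap was small in some deciles, with 19.5% against 19.3% in decile 4 and 35.5% against 35.1% in decile 7. No interval was computed for this difference. In the adult deciles 2 to 6, peaks of regions called at all 3 ages had a lower p300 share than adult-only peaks, for example 22.6% against 29.4% in decile 6. In the strongest decile the share was 84.3% for regions called at all 3 ages (7116 peaks) and 60.2% for adult-only regions (133 peaks), a difference of 24.1 percentage points (95% interval 15.8 to 32.5). Decile 9 differed in the same direction by 7.24 points (2.88 to 11.6). The 95% intervals of the differences in deciles 1, 7 and 8 included 0.

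**Figure D4:**
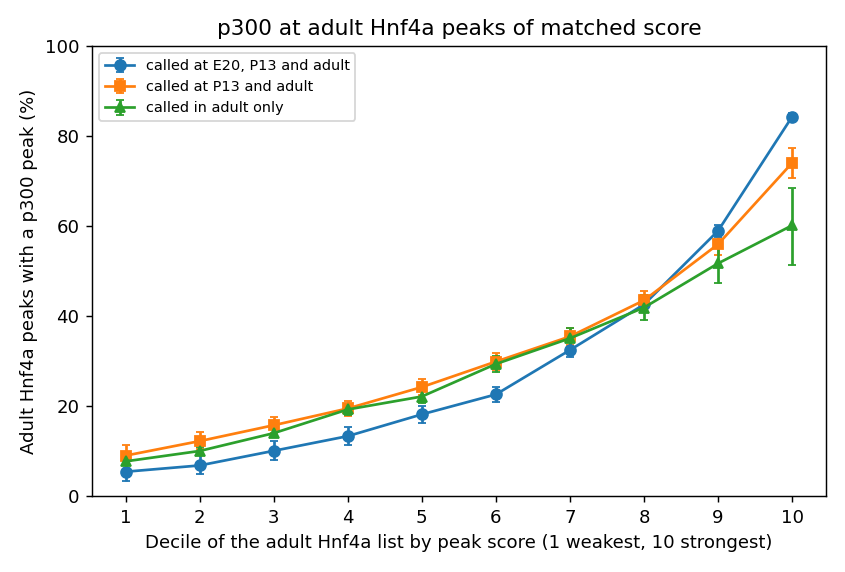
Percentage of adult Hnf4a peaks with a p300 peak, by decile of the adult list from the weakest (1) to the strongest (10) score, for peaks in regions called at all 3 ages, at P13 and adult, or in adult only, with exact 95% binomial intervals. In the strongest decile the shares are 84.3%, 74.0% and 60.2%, and in deciles 1 to 7 regions called at all 3 ages have the lowest share. In deciles 1 and 7 the interval of the difference from adult-only peaks includes 0.

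Hnf4a binding was unevenly spread over the chromosomes. In adult, chromosome 10 held 49.8 peaks per Mb, chromosome 12 held 42.6 and chromosome 19 held 42.2, whereas chromosome 2 held 22.4 and the X chromosome 8.44. The adult list was between 1.95 times (chromosome 20) and 2.21 times (chromosome 17) as long as the E20 list on every autosome, and 3.21 times as long on X. The X chromosome carried 1.09% of E20 peaks (95% interval 0.989 to 1.20), 1.52% (1.41 to 1.63) of P13 peaks and 1.67% (1.58 to 1.76) of adult peaks. In the adult list limited to the length of the E20 list, X carried 1.12% (1.01 to 1.23) of the peaks.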

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

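The common floor and the 500 bp distance between centres were chosen only after seeing the data, and the cause of the shifts below was not tested except where a shorter list sets them by construction. The order of the peak numbers, E20 below P13 below adult, held under each threshold tried on the called peaks. The adult list was between 1.92 times (common floor of 9.4 tags per 10 M) and 2.60 times (at least 17.3 tags per 10 M) as long as the E20 list. In the latter case 19500 E20, 33832 P13 and 50688 adult peaks were left. Neither floor on the tag count corrects for the differing share of tags in peaks. Putative peaks before the authors' filters did not keep the order, with 128649 at E20 and 124949 at P13. Dropping unplaced sequences changed nothing, since none of the lists held any. Summaries by distance to a transcription start site, by gene list and by motif, with their alternatives, were not run for lack of an rn4 annotation and sequence in the material used here. No paired analysis was possible because each group had 1 library. The depth of 1 library per age limits which weak sites could be called, so a missing peak is not a measured absence of binding.

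With reciprocal 50% overlap, E20 peaks were shared with P13 at 73.8% and with adult at 74.9%, P13 peaks with E20 at 53.6% and with adult at 81.5%, and adult peaks with E20 at 35.8%, with P13 at 53.6% and with p300 at 27.7%, while p300 peaks were shared with adult Hnf4a at 52.1%. The p300 share was then 46.1% of regions called at all 3 ages, 16.3% of adult-only regions, 20.5% of regions in adult and not at E20, and 13.7% of regions at E20 and not in adult. The median score percentile of shared peaks exceeded that of the others by 38.5 points in the adult list (against E20) and 26.7 points in the E20 list (against adult). With centres within 100 bp, adult Hnf4a and p300 shared 31.5% and 59.2% of their peaks, and p300 lay at 14.3% of regions at E20 and not in adult. With centres within 500 bp, E20 peaks were shared with P13 at 79.6% and with adult at 83.5%, P13 peaks with E20 at 59.8% and with adult at 89.8%, and adult peaks with E20 at 43.6% and with P13 at 62.7%.

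In the 50% of each list with the higher scores, E20 peaks were shared with P13 at 80.4% and with adult at 81.2%, P13 peaks with E20 at 58.4% and with adult at 89.0%, adult peaks with E20 at 38.8%, with P13 at 58.5% and with p300 at 32.8%, and p300 peaks with adult Hnf4a at 61.5%. By construction fewer regions were left: 14310 at all 3 ages, 15326 in adult only, 24409 in adult and not at E20, 3546 at E20 and not in adult, and 1837 at P13 only. Their p300 shares were 46.8% at all 3 ages, 24.1% in adult only, 25.7% in adult and not at E20, and 7.92% at E20 and not in adult.

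With lists of equal length, set for each comparison by its shortest list, E20 and P13 shared 67.7% of peaks, E20 and adult 60.2%, P13 and adult 72.8%, and adult Hnf4a and p300 47.8%, with both directions equal at this rounding. Regions numbered 7717 in adult only and 15075 both in adult and not at E20 and at E20 and not in adult. Their p300 shares were 56.7% at all 3 ages, 34.6% in adult only, 39.0% in adult and not at E20, and 13.5% at E20 and not in adult. With the common floor, E20 peaks were shared with adult at 77.9%, P13 peaks with E20 at 56.6% and with adult at 85.1%, and adult peaks with E20 at 40.5% and with P13 at 59.5%. The p300 share was then 50.7% at all 3 ages, 20.8% in adult only and 25.7% in adult and not at E20. Under all of these settings the p300 share was highest at regions called at all 3 ages among the 4 kinds named here.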

Other observations

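The test on sequencing depth, the bins, and the checks that use a 500 bp distance, a 20-fold enrichment, an expected p300 share or X peaks by decile were chosen only after results were seen. Adult Hnf4a peaks were concentrated in clusters. The densest bin of 100 kb, on chromosome 10 from 11000001 to 11100000, held 32 adult peaks, 21 P13 peaks, 15 E20 peaks and 18 p300 peaks. Chromosome 5 from 62000001 to 62100000 held 31 adult, 28 P13 and 12 E20 peaks, and chromosome 8 from 112800001 to 112900000 held 31, 20 and 12. Uniform placement of the adult peaks gave at most 16 in a bin over 20 draws, a number that 540 bins exceeded, and these bins held 13.5% of the adult peaks. Of the adult peaks without an overlapping E20 peak, 53.8% had an E20 centre within 10 kb, against 18.4% of all adult peaks after a single shift.

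In some bins of 1 Mb few E20 peaks were called beside many adult peaks. Among bins with at most 2 E20 regions, the highest number of adult regions was found on chromosome 15 from 5000001 to 6000000, with 0 at E20, 8 at P13 and 30 in adult. Its adult peaks were weak, at a median score percentile of 30.4, and 1 of the 30 overlapped a p300 peak. Among all adult peaks of deciles 3 and 4, 15.9% and 21.1% had an E20 peak, so few E20 calls at such scores do not show an absence of binding. On chromosome 1 from 178000001 to 179000000 there were 2 E20, 9 P13 and 24 adult regions, with a median score percentile of 47.2. On X from 55000001 to 56000000 there were 2, 9 and 22, and 8 of the 22 adult peaks overlapped a p300 peak. These bins were picked for their low E20 number, and no expectation for such a choice was computed. The most regions called at E20 and not in adult in a bin were 20, found on chromosome 10 both from 87000001 to 88000000, among 74 E20 regions and beside 108 adult regions, and from 109000001 to 110000000, among 65 E20 regions.

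The adult list was 2.09 times as long as the E20 list, and depth as the cause is argued against by the adult library holding 0.708 times the E20 tags. A single enrichment factor applied to all peaks was examined in the strongest decile of adult peaks. Of these, 10.55% (95% interval 9.89 to 11.2) had no overlapping E20 peak, above a bound of 5% set beforehand. With centres up to 500 bp apart allowed and at least 20-fold enrichment over the adult input required, 8.12% (7.50 to 8.79) still lacked one. This cannot decide the question, because the bound was not computed from such a factor. Sites that the E20 comparison with input removed also count as lacking a peak. For the peaks called at E20 and not in adult, weakness near the calling limit cannot be told apart from loss of binding: 1.86% of the strongest decile of E20 peaks lacked an overlapping adult peak, above a bound of 1% set beforehand that did not allow for displaced centres, but 0.944% (0.662 to 1.30) lacked an adult centre within 500 bp. Age itself, including any change in the cell makeup of the kidney, and an enrichment in the 1 E20 library that varied between sites stay open, as neither was tested. The authors' filter against input rests on 1 input library per age, and these input libraries were not compared.

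The higher p300 share at regions called at all 3 ages than at adult-only regions, 49.0% against 18.1% of adult peaks, may follow in part from peak strength. Given the adult-only shares of the same score deciles, the peaks of regions called at all 3 ages would have 42.6% with p300, which leaves 6.34 percentage points. Only 3 deciles had a higher share at all 3 ages. The largest gap, 24.1 points, was in the strongest decile, where the expected share rests on 133 adult-only peaks. The mean difference over deciles was 0.338 points, but it averages 5 deciles with an interval below 0 and 2 with an interval above 0, so strength as the whole cause cannot be told apart from a difference between the classes. For the strongest decile, score differences within the decile are argued against as its cause, since the difference was 23.17 points (95% interval 13.5 to 32.8) over 8 finer score classes. These classes had equal weight, and each had a higher share at all 3 ages, but the gaps were uneven. The shares were 70.1% against 59.3% in the weakest class, with 27 adult-only peaks, and 87.7% against 40.0% in a class with 5. This difference rests on few adult-only peaks (133 in the decile, of which those in finer classes with fewer than 5 were left out), the ceiling of the score hides differences in strength above it, and no biological explanation was tested.

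The lower X chromosome share at E20 may reflect which peaks a shorter list holds, because the adult list limited to the E20 length had an X share of 1.117%, inside the E20 interval. Adult X peaks overlapped an E20 peak less often (25.9%) than autosomal ones (38.1%), and autosomal peaks of the same adult score deciles had 28.53%. That expectation lay narrowly above the upper limit of the X interval, 28.38%, and the difference from it was -2.60 points (95% interval -4.97 to -0.227). This cannot decide whether weaker scores are the whole cause, because scores were not matched within deciles. The deciles went both ways, with X above the autosomes in 4 and below in 6, although the interval of the difference lay below 0 in 3 deciles and above 0 in 0. The number of X copies, which could differ between the unsexed young kidneys and the male adult, was not tested.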
